A study of Mus musculus with 10 samples.

How the data were processed

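The series holds 10 single-colour Affymetrix arrays of RNA from mouse dendritic cells that were grown from bone marrow, with 1 array for each condition. Per the labels, 5 arrays came from wild-type cells and 5 from CD14-deficient cells. Within each genotype, 1 culture was left unstimulated and harvested 24 h after plating, 2 received LPS at 1 µg/ml for 48 or 60 h, and 2 received LPS with 50 nM thapsigargin for 48 or 60 h. Per the labels, RNA integrity numbers ran from 8.4 to 10, and 0.3 µg of total RNA gave between 15 and 53.1 µg of biotinylated cRNA.

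The values analysed were the deposited intensity of each probe set, a linear MAS5 signal computed by the authors. MAS5 is named in the submitters' processing notes, and its version and scaling target are not given in the sources used here. The values were positive, had no missing entries and covered 22690 probe sets, of which 64 were control probe sets. The 2% trimmed means of the deposited columns ran from 444 to 553, a ratio of 1.25, above the limit of 1.2 that had been set for using the values without scaling. Each array was therefore multiplied to the same 2% trimmed mean of 509. Scaled signals under the pooled 25th percentile, 13.4, were raised to that floor, and log2 was taken.

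Of the 22690 probe sets, 20393 carried 1 gene symbol in the platform table, 691 carried several and 1606, controls included, carried none. Of the 20393, 20364 matched the mouse RefSeq gene table (GRCm38.p6, used for names only) by Entrez ID, and the match changed 0 symbols. Probe sets with several or no symbols and the control probe sets were kept out of the gene tests. Each gene was represented by its probe set with the highest mean over the 10 arrays. A gene was kept when its scaled signal was above the pooled median, 99.2, on at least 2 of the 10 arrays, which left 7474 of 12393 genes. A MAS5 signal near or under the floor does not separate a low level from background, so a fold against a group at the floor on all of its arrays is given as a lower bound.

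All 10 arrays entered 1 linear model per gene in limma 3.58.1 under R 4.3.3, with 6 levels for genotype and treatment and a term for 60 h against 48 h. Variances were moderated by eBayes with an intensity trend, from 3 residual degrees of freedom and a prior of 2.95. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 7474 genes within each comparison, with a threshold of 0.05. No condition was repeated, so the residual spread is how far the 4 stimulated conditions depart from a common shift between 48 and 60 h, plus array noise. The p-values therefore do not cover the spread between cultures or between mice. Each unstimulated condition is a single array and was assumed to vary like the others. Errors given after ± are standard errors of the log2 change from this model. The model assumes 1 spread per gene for all conditions. Yet 1297 genes were 2-fold apart between 48 and 60 h in CD14-deficient LPS cells, against at most 491 in the other stimulated conditions. Standard errors and p-values can thus be too small where the CD14-deficient LPS arrays enter a comparison and too large where they do not. No sample was left out, and the small number of arrays limits the precision of every value.

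The comparisons were the LPS response in each genotype, wild type against CD14-deficient cells under LPS, thapsigargin under LPS in each genotype, the differences of these responses between genotypes, genotype and thapsigargin over the 8 stimulated arrays, 60 h against 48 h, and the genotypes unstimulated. Genes that changed 2-fold in 1 direction at both 48 and 60 h were counted without a model, and genes 2-fold apart in opposite directions at the 2 times were counted as the error of that description, except for the LPS responses, whose 2 times share 1 unstimulated array. Genes were called thapsigargin-restored when they were at least 2-fold higher in wild-type than in CD14-deficient LPS cells at both times and at least 2-fold higher in CD14-deficient cells with thapsigargin than without it at both times. Both conditions use the same CD14-deficient LPS arrays, so the count was set beside 100 simulations without effects that shared those arrays, at both times and at a single time, and beside the product of the separate counts over the number of genes. The simulations gave each gene the same spread on all arrays.

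Before the data were examined, 26 gene lists were fixed for calcium and NFAT signalling, LPS recognition, apoptosis, stress responses, dendritic cell maturation, inflammation, interferon response, cell division, glycolysis, cell types and housekeeping. Each list with at least 3 tested members was compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists within a comparison. The estimated correlation and its test rest on 3 residual degrees of freedom and can hardly call any list. A list that did not pass it is therefore not shown to be unchanged. Members were also counted after adjustment over the list alone. A further 5 lists, for sterol synthesis, amino acid supply, acute phase proteins, migratory dendritic cells and lysosomal and matrix genes, were written after the principal components had been seen.

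Named genes followed a rule fixed before the data were examined. For each of the 5 main comparisons, it took up to 10 highest and 10 lowest genes by log2 change among those past the threshold, 2-fold in the same direction at both times and above the floor on both sides. Where fewer than 10 passed, genes with the largest t statistics among those 2-fold at both times filled the list and are given as values that did not pass. It also took up to 4 members of each list, up to 10 restored genes and 5 of the mirror set, and always Cd14, Nr4a1, Ddit3, Gadd45g and Tia1, the last 4 being genes that the study is remembered to have followed up.

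The model was tested on simulated data in which 200 of the 7474 genes were given a known change on top of normal noise with the spread estimated for each gene. The noise was drawn independently per gene, so these data hold no departure of a whole array like that of the CD14-deficient LPS array at 48 h. It had the same spread on all arrays, so the recovered shares do not cover the larger spread in CD14-deficient LPS cells. At 4-fold, the model recovered 79.0% of the changed genes for LPS in wild type, 87.5% for wild type against CD14-deficient cells, 88.5% for thapsigargin in CD14-deficient cells and 28.5% for the difference of LPS responses. Beside these 158, 175, 177 and 57 recovered genes, it called 15, 9, 12 and 8 unchanged genes. At 2-fold it recovered 0% in each of these 4 comparisons.

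The alternatives tried were quantile normalization, no floor, a pseudocount in place of the floor, no filter, a strict filter at the pooled 75th percentile, the mean of all probe sets of a gene, no intensity trend, no 60 h term, a fit of the 8 stimulated arrays, other fold thresholds, an estimated correlation for the lists, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with tables read by pandas 2.3.3.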

Results

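Gene expression was measured on 10 arrays in dendritic cells grown from the bone marrow of wild-type mice and of mice lacking CD14, the co-receptor that passes LPS to TLR4. The series' stated aim was to find apoptosis genes controlled by NFAT, a calcium-dependent transcription factor, in cells activated by LPS. Thapsigargin, which blocks the calcium pump of the endoplasmic reticulum and raises cytosolic calcium, was added to restore the calcium signal in cells without CD14. Each genotype had 1 unstimulated array, 2 LPS arrays at 48 and 60 h and 2 arrays with LPS and thapsigargin at 48 and 60 h. There were no replicates of any condition and no arm with thapsigargin alone. The 2% trimmed mean signal of the deposited columns ran from 444 to 553, and 7474 genes passed the filter on dim signals. The genotype was plain in the data: the scaled Cd14 signal was 1499 in unstimulated and between 15538 and 17729 in stimulated wild-type cells, and between 1.85 and 7.35, under the floor of 13.4, on all 5 CD14-deficient arrays.

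The first principal component held 57.1% of the variance and parted unstimulated from stimulated cells. On it, the CD14-deficient LPS arrays scored −9.19 and −21.23, between the unstimulated arrays at −74.49 and −69.00 and the other stimulated arrays at 20.79 to 35.58. The second component, 17.3%, held the CD14-deficient LPS array at 48 h at 60.42, while the other 9 arrays lay between −25.02 and 5.12. In that array the macrophage markers were lower than at 60 h by a median log2 of −1.87 (13 of 13 tested members), and its cRNA yield, 15 µg, was the lowest of the 10. Its 2 control probe sets for 18S rRNA had scaled signals of 114 and 269. They were 217 and 396 on the wild-type LPS array at 60 h, next lowest in yield at 19 µg, and between 1426 and 11926 on the other 8 arrays. Both low arrays enter the comparison of the genotypes under LPS, and the wild-type one lay at −6.77 on the second component. Within conditions, 1297 genes were 2-fold apart between 48 and 60 h in CD14-deficient LPS cells, 491 in wild-type LPS cells, 189 in CD14-deficient and 115 in wild-type cells with thapsigargin.

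**Figure D1:**
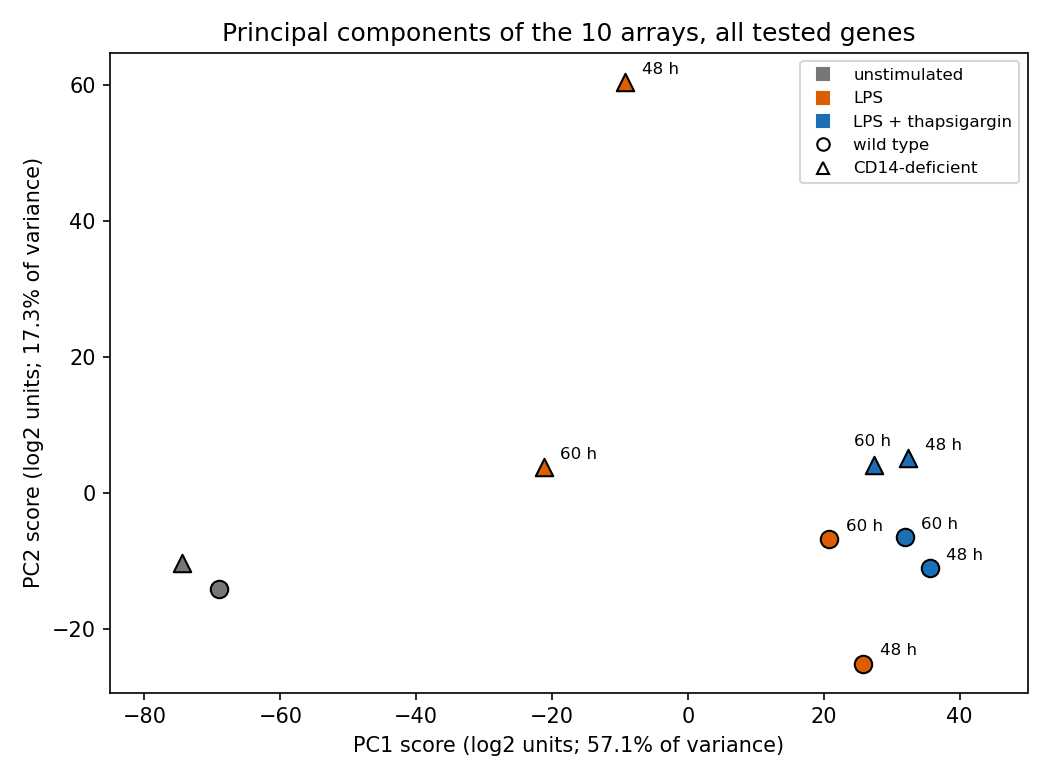
Scores of the 10 arrays on the first component (horizontal axis, log2 units, 57.1% of the variance) and the second (vertical axis, log2 units, 17.3%), with 1 point per array, colour for treatment and shape for genotype. The CD14-deficient LPS array at 48 h lies alone at 60.42 on the second component, and the CD14-deficient arrays with thapsigargin lie near the wild-type stimulated arrays on the first.

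The LPS response in wild-type cells gives the reference for what CD14-deficient cells lack. LPS raised 18 of 32 inflammatory, 20 of 33 interferon-response and 13 of 23 maturation genes and lowered 22 of 27 cell division genes, while none of these lists passed with an estimated correlation (adjusted p = 0.264, and 0.620 for maturation). Il6, an inflammatory cytokine, rose by log2 6.56 ± 0.42 (adjusted p = 0.00161) between the 1 unstimulated array and the 2 LPS arrays, and Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 6.54 ± 0.19 (adjusted p = 0.000315). Hamp, which encodes the iron hormone hepcidin, rose by 7.94 ± 0.38, Cxcl1, a neutrophil attractant, by 6.15 ± 0.34, and U90926 by 8.19 ± 0.28. The mannose receptor gene Mrc1 fell by 6.00 ± 0.89 (adjusted p = 0.0124), Rrm2, a subunit of the enzyme that makes deoxynucleotides, fell by 5.93 ± 0.35, and Ccna2, a cyclin of DNA replication, fell by 5.22 ± 0.30. Cd14 itself rose by 3.41 ± 0.23 (adjusted p = 0.00173).

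Other genes with large rises in wild-type cells were Vnn3 (6.93 ± 0.79), the acute phase gene Orm1 (6.20 ± 0.73), Tm4sf1 (6.19 ± 0.39), Ptges, which completes prostaglandin E2 synthesis (5.76 ± 0.41), and Mucl1 (5.55 ± 0.34). Other large falls were those of S100a9, a neutrophil calcium-binding protein (−6.11 ± 1.14), Ltb (−5.44 ± 0.87), Pclaf (−5.19 ± 0.42), the adhesion gene Cdh1 (−5.08 ± 0.56), Rad51ap1 (−5.02 ± 0.59), Shcbp1 (−4.86 ± 0.46) and Clec4b1 (−4.79 ± 0.63). Of 7474 genes, 575 rose and 616 fell, 1191 in all, a balance that turned with quantile normalization (672 and 597) and a strict filter (416 and 354). At both times, 608 genes were 2-fold higher and 728 were 2-fold lower, and 1 was 2-fold apart in opposite directions, but both times are set against the same unstimulated array, so part of this agreement is built in.

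Among the fixed lists in wild-type cells, 20 of 33 interferon-response genes rose, 0 fell and 13 did not pass (26 rose when adjusted over the list alone). Their median log2 change was 1.62 (camera adjusted p = 4.5e-13). Examples were Irf7, a transcription factor of interferon induction (3.48 ± 0.30), and Oasl1 (3.41 ± 0.33), and Mx2, an antiviral GTPase at the floor without LPS, was at least 37.3-fold higher. Of 32 NF-κB and inflammatory genes, 18 rose and 14 did not pass (20 rose when adjusted over the list alone). Their median was 1.65 (camera adjusted p = 9.5e-13). Csf3, the granulocyte growth factor, was at least 193-fold higher. Of 27 cell division genes, 22 fell and 5 did not pass (23 fell and 1 rose when adjusted over the list alone). Their median was −3.05 (camera adjusted p = 4.9e-14). Ccnb2 fell by 4.59 ± 0.50, and Ube2c was at least 98.0-fold lower. For each of these 3 lists the adjusted p = 0.264 with an estimated correlation. Of 23 maturation genes, 13 rose, 1 fell and 9 did not pass (13 and 1 when adjusted over the list alone). Their median was 1.21 (camera adjusted p = 3.0e-06, adjusted p = 0.620 with an estimated correlation). Il12a and Il12b, the subunits of interleukin 12, rose by 5.52 ± 0.28 and 4.38 ± 0.46, and Ido1, a tryptophan-degrading enzyme, rose by 2.80 ± 0.49.

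The camera test with the preset correlation did not call the apoptosis and stress lists in wild-type cells, while single members passed. Of 9 proapoptotic Bcl2 family genes, 0 passed, also when adjusted over the list alone, and Bnip3 had the smallest adjusted p at 0.0521 (1.55 ± 0.40). That count rests on the probe set used for each gene. On probe sets not used, Bcl2l11 had log2 changes from 0.21 to 2.51, against 0.52 on the one used. Bid had −2.21 on the one not used, against −0.17. Of 14 survival genes, 4 rose, 1 fell and 9 did not pass (4 and 1 when adjusted over the list alone). Cflar, an inhibitor of caspase 8, rose by 2.27 ± 0.25, the kinase gene Pim3 by 3.03 ± 0.25 and Traf1 by 1.96 ± 0.43, while Birc5, which also acts in mitosis, fell by 4.00 ± 0.34. Of 13 death receptor genes, 1 rose (Tnfrsf1b, 1.83 ± 0.22), 1 fell (Dapk1, −1.13 ± 0.22) and 11 did not pass (2 and 1 when adjusted over the list alone). Of 17 caspase and execution genes, 1 rose (the inflammatory caspase Casp4, 2.98 ± 0.26), 1 fell (Htra2, −1.06 ± 0.27) and 15 did not pass (1 and 0 when adjusted over the list alone). Of 19 p53 and damage genes, 5 rose and 14 did not pass (5 rose and 2 fell when adjusted over the list alone), with Ddit4, an inhibitor of mTOR, at 3.82 ± 0.28 and Gadd45a at 2.65 ± 0.25. Of 35 endoplasmic reticulum stress genes, 6 rose, 1 fell and 28 did not pass (8 and 2 when adjusted over the list alone), among them Ppp1r15a (1.93 ± 0.38) and Atf4 (1.78 ± 0.16), which act in the stress response to unfolded proteins. Of 10 heat shock genes, 4 rose and 6 did not pass (4 rose and 2 fell when adjusted over the list alone), among them Hspa1b (3.98 ± 0.28) and Hspa1a (3.83 ± 0.39). Of the 4 genes the study is remembered to have followed up, Ddit3 (2.86 ± 0.45) and Gadd45g (2.19 ± 0.38) rose and 2 did not pass (3 rose when adjusted over the list alone). They are treated as chosen on these samples, so the count is not independent evidence. Nr4a1 had a log2 change of 2.11 ± 0.56 (adjusted p = 0.0543) and Tia1 of −1.05 ± 0.58 (adjusted p = 0.264).

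Of 13 NFAT target genes in wild-type cells, 4 rose, 2 fell and 7 did not pass (5 and 4 when adjusted over the list alone). Il10, an anti-inflammatory cytokine at the floor without LPS, was at least 17.9-fold higher, and Egr2 fell by 3.41 ± 0.61. Of 17 genes of the NFAT signalling machinery, 1 rose (Src, 1.18 ± 0.30), 3 fell and 13 did not pass (1 and 4 when adjusted over the list alone), the 3 being the kinase Fgr (−3.50 ± 0.34), Nfatc1 (−1.76 ± 0.27) and the phospholipase Plcg2 (−1.51 ± 0.19). Of 8 LPS receptor genes, Cd14 rose, the adaptor Myd88 fell by 1.10 ± 0.24 and 6 did not pass (2 rose and 1 fell when adjusted over the list alone). Of 11 MHC class II and antigen presentation genes, 2 fell and 9 did not pass (2 fell when adjusted over the list alone), namely Cd209a (−3.24 ± 0.64) and H2-DMa (−1.48 ± 0.25). Of 18 glycolysis and hypoxia genes, 2 rose and 16 did not pass (4 rose and 2 fell when adjusted over the list alone), namely the vessel growth factor Vegfa (3.65 ± 0.33) and Adm (2.77 ± 0.44). Of 14 dendritic cell markers, Irf8 rose by 1.95 ± 0.27, Clec10a and Cd209a fell and 11 did not pass (1 rose and 5 fell when adjusted over the list alone). Of 13 macrophage markers, 1 rose (Adgre1, 1.59 ± 0.27), 2 fell (Mrc1 and the complement gene C1qa, −3.58 ± 0.88) and 10 did not pass (1 and 4 when adjusted over the list alone). Of 8 neutrophil markers, the iron-binding protein gene Lcn2 rose by 5.19 ± 0.29, 3 fell, among them Ngp (−2.34 ± 0.37), and 4 did not pass (2 and 3 when adjusted over the list alone). Of 5 mast cell and basophil markers, 1 rose, the histamine-producing enzyme gene Hdc, at least 96.3-fold, and 4 did not pass (1 rose when adjusted over the list alone). Of 5 stromal markers, 3 rose, 1 fell (Fn1, −2.42 ± 0.27) and 1 did not pass (3 and 1 when adjusted over the list alone), with the matrix genes Dcn and Lum at least 118-fold and 10.3-fold higher. Of 11 housekeeping genes, the lysosomal enzyme gene Gusb fell by 2.35 ± 0.20 and 10 did not pass (1 fell when adjusted over the list alone). Lists of B cell, T and NK cell and erythroid markers had only 2, 2 and 0 members above the filter and were not tested.

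The unstimulated cells had been in culture for less time than the stimulated ones, so the LPS comparisons also hold time in culture. The wild-type count was 770 under a strict filter, 3271 and 3281 without the CD14-deficient LPS array at 48 or at 60 h, and between 170 and 399 without any single one of the other 6 stimulated arrays.

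In CD14-deficient cells LPS still raised 13 of 32 inflammatory and 10 of 23 maturation genes, while neither list passed with an estimated correlation (adjusted p = 0.492). Il6 rose by log2 6.44 ± 0.42 (adjusted p = 0.00396), Ptgs2 by 5.21 ± 0.19 (adjusted p = 0.000607) and Il12a by 4.69 ± 0.28 (adjusted p = 0.00317). Mrc1 fell by 6.54 ± 0.89, Ccr2, the receptor that draws monocytes to Ccl2, fell by 5.90 ± 0.38, and the neutrophil granule gene Ngp fell by 4.34 ± 0.37. None of the 4 followed-up genes passed, with Nr4a1 at −1.15 ± 0.56 (adjusted p = 0.284), Gadd45g at −0.61 ± 0.38 (0.383), Ddit3 at 0.70 ± 0.45 (0.403) and Tia1 at 0.16 ± 0.58 (0.894). Of 7474 genes, 162 rose and 150 fell, 312 in all, a balance that varied with the processing (76 rose and 239 fell without a filter, 98 and 49 under a strict one, 158 and 166 with a pseudocount, 139 and 169 without the intensity trend).

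Other large rises in CD14-deficient cells were those of Vnn3 (5.73 ± 0.79), Hamp (5.41 ± 0.38), Cxcl1 (4.95 ± 0.34), Igfbp4 (4.80 ± 0.40), the acute phase gene Saa3 (4.78 ± 0.24), Tm4sf1 (4.57 ± 0.39) and Il12b (4.25 ± 0.46). Other large falls were those of Fcrls (−5.56 ± 0.94), Asgr2 (−5.30 ± 0.61), Bex1 (−4.68 ± 0.84), Cldn1 (−4.48 ± 0.50), Pld4 (−4.20 ± 0.61), Klk1b21 (−4.14 ± 0.60) and Clec4b1 (−3.97 ± 0.63). Of 23 maturation genes, 10 rose and 13 did not pass (21 rose when adjusted over the list alone). Their median was 1.78 (camera adjusted p = 1.4e-13, adjusted p = 0.492 with an estimated correlation). They included Ido1 (4.03 ± 0.49) and Cd40, a costimulatory receptor (2.59 ± 0.44). Of 32 NF-κB and inflammatory genes, 13 rose, 2 fell and 17 did not pass (20 and 3 when adjusted over the list alone). Their median was 1.24 (camera adjusted p = 4.2e-07, adjusted p = 0.492 with an estimated correlation). Of 27 cell division genes, 18 fell and 9 did not pass (23 fell when adjusted over the list alone). Their median was −2.19 (camera adjusted p = 7.1e-18, adjusted p = 0.405 with an estimated correlation). Of 33 interferon-response genes, 4 rose and 29 did not pass (5 rose when adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.0887). The 4 were Irf8 (2.74 ± 0.27), Oasl1 (1.90 ± 0.33), Irf7 (1.66 ± 0.30) and Gbp2 (1.53 ± 0.17).

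The camera test also called 13 macrophage markers lower in CD14-deficient cells under LPS (median −1.36, 1 fell, 4 when adjusted over the list alone, camera adjusted p = 0.00213), beside the 48 h array in which they were low. It called 35 endoplasmic reticulum stress genes lower (median −0.46, 1 rose, 0 fell, and 1 and 6 when adjusted over the list alone, camera adjusted p = 0.0183). It called 14 survival genes higher (median 0.59, 2 rose, 1 fell, and 4 and 1 when adjusted over the list alone, camera adjusted p = 0.0257). These 3 lists had an adjusted p = 0.726 with an estimated correlation. The 5 stromal markers were also called higher (median 2.69, 3 rose, also when adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.492 with an estimated correlation). Of the survival genes, Cflar (1.74 ± 0.25) and Pim3 (1.62 ± 0.25) rose. The count of 312 was 147 under a strict filter, 1190 and 2883 without the CD14-deficient LPS array at 48 or at 60 h, and between 22 and 42 without any single one of the other 6 stimulated arrays.

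The responses of the genotypes overlapped: 140 genes rose in both, where independent lists would share 12.5, and 134 fell in both, where they would share 12.4, and 0 were called in opposite directions. Of the 1191 genes called in wild-type cells, 1136 had the same sign in CD14-deficient cells and 1062 a smaller change there, a count raised by choosing genes on their wild-type change. Of the 312 called in CD14-deficient cells, 177 had a larger and 135 a smaller change in wild-type cells. Tested per gene, the difference of the LPS responses passed in 0 genes by limma, with 613 at an unadjusted p under 0.05. That count was 192 without a filter, 1 without a floor, 17 without the CD14-deficient LPS array at 48 h and 1367 without that at 60 h.

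Wild-type and CD14-deficient cells under LPS were compared directly to find genes that differ with CD14. The background strain and sex of the mice were not used, and differences present without LPS also enter: Erdr1 and Ccl7 were apart by at least log2 4.04 and 1.10 in each of the 5 matched pairs, the unstimulated pair included. In wild-type cells 18 of 33 interferon-response, 9 of 32 inflammatory and 4 of 10 heat shock genes were higher and 8 of 27 cell division genes were lower, while none of these lists passed with an estimated correlation (adjusted p = 0.273). Ccl7 and Ccl2, which attract monocytes, were higher by log2 4.83 ± 0.34 (adjusted p = 0.00847) and 3.52 ± 0.17 (adjusted p = 0.00168), and Csf3 by 4.79 ± 0.23 (adjusted p = 0.00168), with 2 arrays against 2. Gadd45g, a stress-induced growth arrest gene, was higher by 2.97 ± 0.31 (adjusted p = 0.0165), Nr4a1, an orphan nuclear receptor induced by calcium, by 2.41 ± 0.45 (adjusted p = 0.0436), and Ddit3, a transcription factor of unresolved endoplasmic reticulum stress, by 2.22 ± 0.37 (adjusted p = 0.0348). Tia1, an RNA-binding protein gene, did not pass at −1.28 ± 0.47 (adjusted p = 0.153).

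Of 7474 genes, 195 were higher and 192 lower in wild-type LPS cells, 387 in all. Cd14 was at least 1186-fold higher, and the other genes with the largest differences upward were Erdr1 (5.38 ± 0.24), Emp1 (3.91 ± 0.41), the mitochondrial nucleotide kinase gene Cmpk2 (3.81 ± 0.54), Ms4a4c (3.65 ± 0.36), Ifit3 (3.51 ± 0.39), Gprc5b (3.49 ± 0.30) and Hspa1b (3.49 ± 0.23). Those downward were Septin4 (−3.73 ± 0.42), the complement protease gene C1s1 (−3.71 ± 0.46), Pclaf (−3.17 ± 0.34), Ccna2 (−3.12 ± 0.24), Flt3 (−3.05 ± 0.52), Hepacam2 (−3.05 ± 0.55), Aif1 (−2.94 ± 0.45), the immunoglobulin gene Igha (−2.81 ± 0.32), Rrm2 (−2.80 ± 0.29) and Rad51ap1 (−2.72 ± 0.48). At both times, 164 genes were 2-fold higher and 247 were 2-fold lower, while 108 were 2-fold apart in opposite directions.

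By list, 18 of 33 interferon-response genes were higher, 0 lower and 15 did not pass (25 higher and 1 lower when adjusted over the list alone). Their median was 1.60 (camera adjusted p = 1.8e-15). They included Ifit2 (3.15 ± 0.57) and the antiviral enzyme gene Rsad2 (3.08 ± 0.49). Of 32 NF-κB and inflammatory genes, 9 were higher and 23 did not pass (14 when adjusted over the list alone). Their median was 0.79 (camera adjusted p = 1.1e-08). Among them was Il10 (2.88 ± 0.58). Of 35 endoplasmic reticulum stress genes, 5 were higher and 30 did not pass (14 higher and 1 lower when adjusted over the list alone). Their median was 0.53 (camera adjusted p = 1.2e-05). Atf4 was higher by 1.23 ± 0.13 and the chaperone gene Hsp90b1 by 0.99 ± 0.18. Of 10 heat shock genes, 4 were higher and 6 did not pass (6 when adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.000527). Among them was Hspa1a (3.20 ± 0.32). Of 19 p53 and damage genes, 6 were higher and 13 did not pass (6 when adjusted over the list alone). Their median was 0.39 (camera adjusted p = 0.0104). Among them were Perp, a p53 target of cell death (1.80 ± 0.22), and Gadd45a (1.19 ± 0.20). Of 27 cell division genes, 8 were lower and 19 did not pass (17 lower and 1 higher when adjusted over the list alone). Their median was −1.30 (camera adjusted p = 2.1e-06). Ube2c was at least 13.3-fold lower. The 4 followed-up genes had a median of 2.32, 3 were higher and 1 did not pass (3 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0217), which is not independent evidence. For all 7 of these lists the adjusted p = 0.273 with an estimated correlation.

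Of 14 dendritic cell markers, 3 were lower and 11 did not pass (5 lower when adjusted over the list alone). Their median was −0.53 (camera adjusted p = 0.0217, adjusted p = 0.325 with an estimated correlation). The 3 were Flt3, a growth factor receptor of dendritic cells, the transcription factor Irf4 (−2.40 ± 0.37) and Cd1d1 (−0.99 ± 0.17). The direction of Irf4 depends on the probe set: another one past the filter on dim signals, with a lower mean signal, gave 1.24 between the genotypes and 2.45 with thapsigargin in CD14-deficient cells, against −2.40 and −1.31 for the one used. Of 11 MHC class II genes, 0 passed (4 lower when adjusted over the list alone). Their median was −0.26 (camera adjusted p = 0.025, adjusted p = 0.382 with an estimated correlation). Among the death genes, Tnfrsf21, death receptor 6, was higher by 1.85 ± 0.24, Tnfrsf1b by 1.21 ± 0.18 and Casp4 by 1.37 ± 0.21, while Htra2 was lower at −1.10 ± 0.22. Of 13 death receptor genes, 2 were higher (3 higher and 1 lower when adjusted over the list alone), of 17 caspase and execution genes 1 was higher and 1 lower (also when adjusted over the list alone), and of 9 proapoptotic Bcl2 family genes 0 passed (also when adjusted over the list alone). That count rests on 1 probe set per gene. Of 5 probe sets for Bcl2l11, which encodes Bim, 1 that was not used gave 1.74 between the genotypes and 2.31 with thapsigargin in CD14-deficient cells, against −0.85 and −0.59 for the one used. The remaining ones went the way of the one used, with −1.23 to −0.33 and −1.14 to −0.20. For Bak1, 1 not used, with a mean signal of 85.3, gave 1.32 and 1.77. The one used, with a mean signal of 592, gave 0.48 and 0.30. Of 13 NFAT target genes, 4 were higher, 2 lower and 7 did not pass (6 and 3 when adjusted over the list alone, camera adjusted p = 0.0881), among them Ptges (3.34 ± 0.33). Of 23 maturation genes, 2 were lower and 21 did not pass (2 when adjusted over the list alone, camera adjusted p = 0.624), namely the chemokine gene Ccl17 (−1.58 ± 0.23) and Socs2 (−1.03 ± 0.20). The count of 387 was 105 without a filter, 1328 and 3309 without the CD14-deficient LPS array at 48 or at 60 h, and between 2 and 7 without any single one of the other 6 stimulated arrays. Without a filter the calls of Gadd45g, Nr4a1 and Ddit3 ended at unchanged log2 differences (adjusted p = 0.0613, 0.138 and 0.117).

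**Figure D2:**
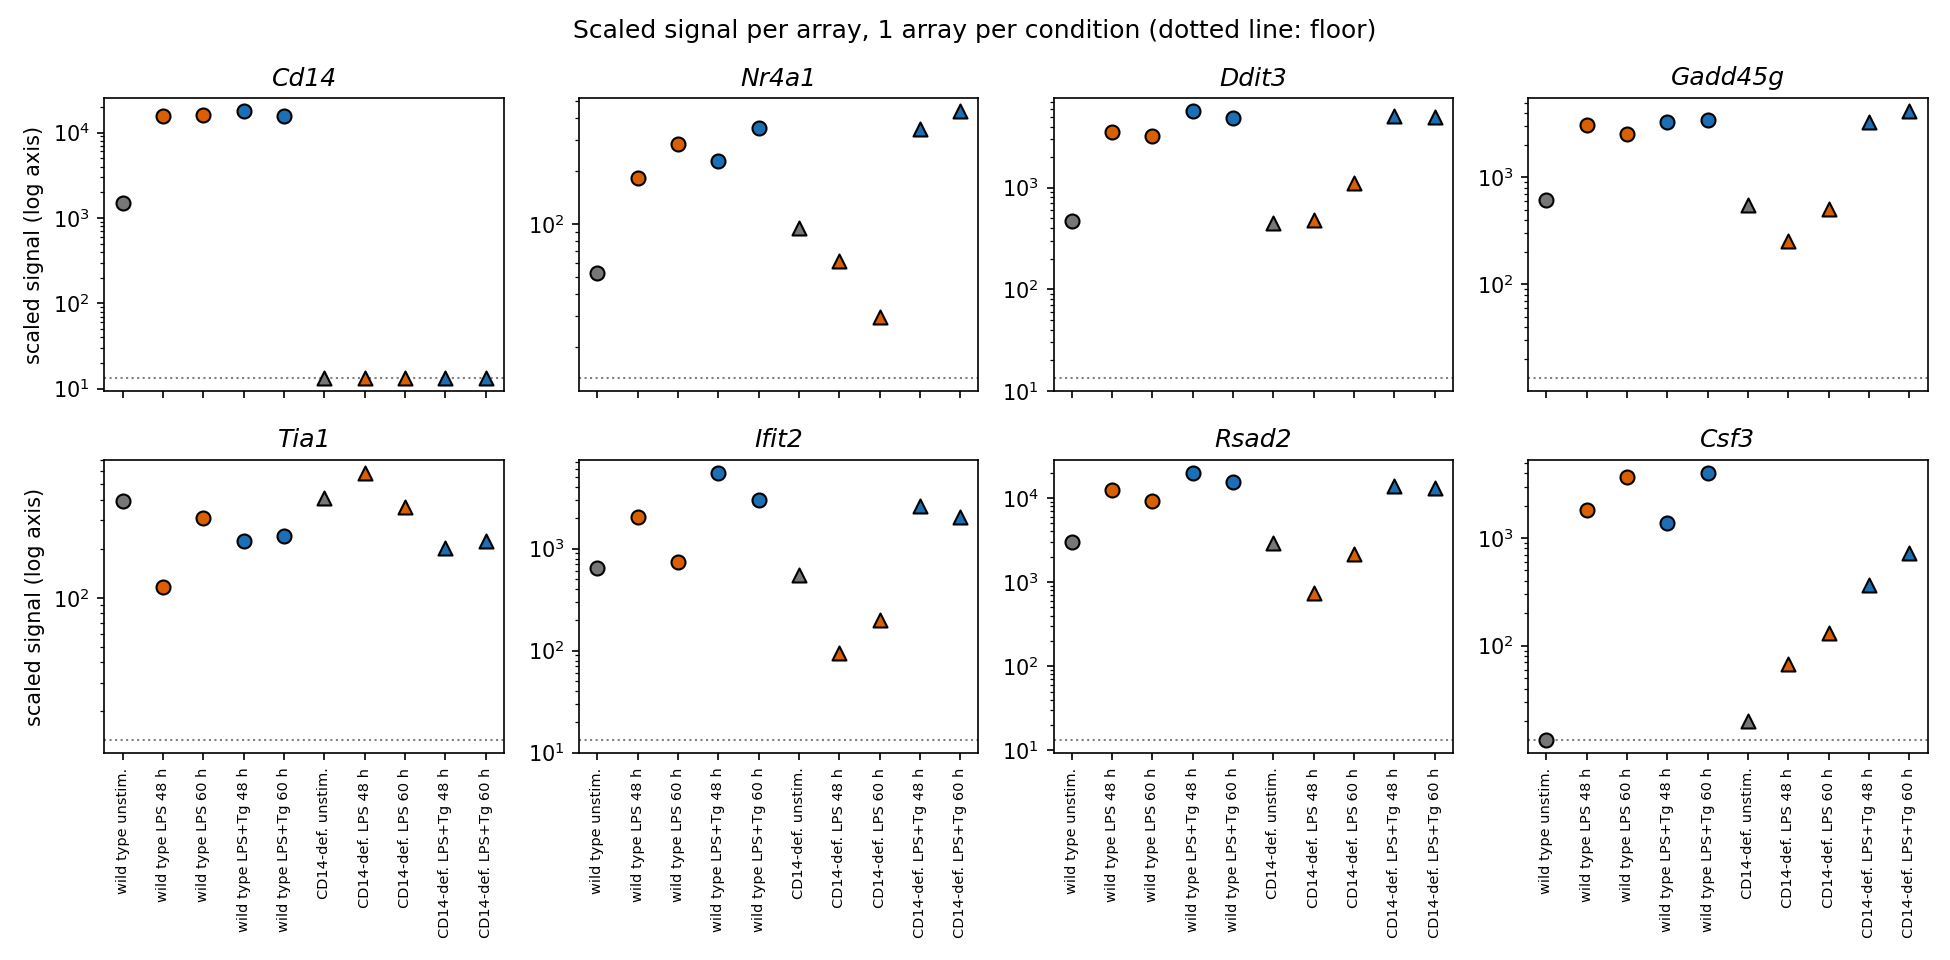
Scaled signal (vertical log axis, arbitrary units) of 8 genes on the 10 arrays, with 1 point per array, circles for wild type and triangles for CD14-deficient cells, and a dotted line at the floor of 13.4, to which lower signals were raised. For Nr4a1, Ddit3 and Gadd45g the CD14-deficient LPS arrays lie below the wild-type LPS arrays and below the CD14-deficient arrays with thapsigargin, and Cd14 is at the floor on all 5 CD14-deficient arrays.

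Thapsigargin in CD14-deficient cells under LPS asks which genes a calcium rise restores. In these cells thapsigargin raised 18 of 33 interferon-response, 11 of 35 endoplasmic reticulum stress and 8 of 19 p53 and damage genes. It lowered 3 of 8 neutrophil markers, and of 27 cell division genes 6 fell and 2 rose, while none of these 5 lists passed with an estimated correlation (adjusted p = 0.249, and 0.289 for cell division). Cmpk2 rose by log2 4.57 ± 0.54 (adjusted p = 0.0160), Perp by 4.20 ± 0.22 (adjusted p = 0.00780) and Ifit2 by 4.07 ± 0.57 (adjusted p = 0.0195), with 2 arrays against 2. Gadd45g rose by 3.37 ± 0.31 (adjusted p = 0.0109), Nr4a1 by 3.18 ± 0.45 (adjusted p = 0.0202) and Ddit3 by 2.79 ± 0.37 (adjusted p = 0.0184), while Tia1 had a value of −1.11 ± 0.47 (adjusted p = 0.188). Hp, which encodes the acute phase protein haptoglobin, fell by 4.66 ± 0.32 (adjusted p = 0.0101) and Flt3 by 3.37 ± 0.52 (adjusted p = 0.0230).

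Of 7474 genes, 256 rose and 239 fell with thapsigargin in CD14-deficient cells, 495 in all. Further rises were those of Ifit3 (3.91 ± 0.39), Ms4a4c (3.49 ± 0.36), Emp1 (3.45 ± 0.41), Rsad2 (3.40 ± 0.49), Gprc5b (3.35 ± 0.30) and Isg20 (3.32 ± 0.64). Further falls were those of Wfdc21 (−4.67 ± 0.48), Aif1 (−3.79 ± 0.45), the immunoglobulin gene Ighm (−3.70 ± 0.49), Gpr84 (−3.66 ± 0.31), U90926 (−3.57 ± 0.23), Pclaf (−3.34 ± 0.34), Ly6i (−3.34 ± 0.61) and Rrm2 (−3.30 ± 0.29). At both times, 207 genes were 2-fold higher and 301 were 2-fold lower, and 48 were 2-fold apart in opposite directions.

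Of 33 interferon-response genes, 18 rose and 15 did not pass (24 rose and 2 fell when adjusted over the list alone). Their median was 1.24 (camera adjusted p = 1.1e-10). Of 35 endoplasmic reticulum stress genes, 11 rose and 24 did not pass (19 rose when adjusted over the list alone). Their median was 0.95 (camera adjusted p = 2.8e-09). Among them were Trib3 (2.31 ± 0.32), Creld2 (1.71 ± 0.33) and Atf4 (1.62 ± 0.13). Of 19 p53 and damage genes, 8 rose and 11 did not pass (10 rose when adjusted over the list alone). Their median was 0.85 (camera adjusted p = 4.2e-06). Among them were Phlda3 (1.69 ± 0.16) and the exonuclease gene Aen (1.36 ± 0.19). Of 8 neutrophil markers, 3 fell and 5 did not pass (5 fell when adjusted over the list alone). Their median was −1.64 (camera adjusted p = 0.00175). The 3 were Mmp9 (−3.60 ± 0.67), Camp (−2.44 ± 0.30) and S100a8 (−1.55 ± 0.22). For these 4 lists the adjusted p = 0.249 with an estimated correlation. Of 27 cell division genes, 2 rose, 6 fell and 19 did not pass (2 and 14 when adjusted over the list alone). Their median was −1.19 (camera adjusted p = 3.5e-06). Among them was Mki67 (−2.85 ± 0.34). Of the 4 followed-up genes, 3 rose and 1 did not pass (3 when adjusted over the list alone, camera adjusted p = 0.0218), which is not independent evidence. For both of these lists the adjusted p = 0.289 with an estimated correlation.

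Of 10 heat shock genes, 4 rose and 6 did not pass (4 when adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.0103). Among them was Hspa1a (2.67 ± 0.32). Of 14 dendritic cell markers, 2 fell and 12 did not pass (4 fell when adjusted over the list alone). Their median was −0.84 (camera adjusted p = 0.0218). For both the adjusted p = 0.316 with an estimated correlation. Of 32 NF-κB and inflammatory genes, 7 rose, 1 fell and 24 did not pass (11 and 5 when adjusted over the list alone, camera adjusted p = 0.135), among them Ccl7 (2.66 ± 0.34), Csf3 (2.45 ± 0.23) and Ccl2 (1.97 ± 0.17). Of 13 NFAT target genes, 2 rose, 1 fell and 10 did not pass (6 and 2 when adjusted over the list alone, camera adjusted p = 0.0696), namely Nr4a1, Ptgs2 (1.77 ± 0.15) and Egr2 (−3.18 ± 0.50). Of 23 maturation genes, 2 rose, 1 fell and 20 did not pass (7 and 5 when adjusted over the list alone), the rises being those of Il23a (2.25 ± 0.35) and Il15 (1.33 ± 0.25), cytokines that act on T cells. On the probe sets used, none of 9 proapoptotic Bcl2 family genes, 13 death receptor genes and 17 caspase and execution genes passed over all genes.

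Thapsigargin is itself a standard inducer of endoplasmic reticulum stress, and no cells received it without LPS. The count of 495 was 153 without a filter, 2150 and 2894 without the CD14-deficient LPS array at 48 or at 60 h, 201 and 198 without either wild-type LPS array, and 0 without any single one of the 4 arrays with thapsigargin.

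In wild-type cells under LPS, where CD14 is present, thapsigargin changed 4 genes past the threshold. Gpr35, a G protein-coupled receptor gene, rose by log2 2.39 ± 0.20 (adjusted p = 0.0374). Tm4sf1 fell by 4.67 ± 0.32, Hp by 4.23 ± 0.32 and U90926 by 3.12 ± 0.23, each with an adjusted p = 0.0315 and 2 arrays against 2. At both times, 82 genes were 2-fold higher, 130 were 2-fold lower and 3 were 2-fold apart in opposite directions. The 4 followed-up genes had values of 0.31 ± 0.45 for Nr4a1, 0.63 ± 0.37 for Ddit3, 0.25 ± 0.31 for Gadd45g and 0.30 ± 0.47 for Tia1, with adjusted p from 0.592 to 0.856.

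Genes 2-fold apart at both times that did not pass in wild-type cells included Perp (2.17 ± 0.22, adjusted p = 0.0763), Phlda3 (1.24 ± 0.16), Aen (1.15 ± 0.19), the ER degradation gene Derl3 (2.56 ± 0.43), Tnfsf8 (3.02 ± 0.37), Irgm2 (1.44 ± 0.19), Sdcbp2 (1.72 ± 0.21), Sncg (2.88 ± 0.39) and Slc13a3 (2.29 ± 0.31). On the lower side they were Saa3 (−2.09 ± 0.20, adjusted p = 0.0669), Tgfbi (−3.33 ± 0.38), Gpr84 (−2.59 ± 0.31), Lox (−2.84 ± 0.35), Wfdc21 (−3.82 ± 0.48), Fabp4 (−2.52 ± 0.33) and S100a8 (−1.63 ± 0.22). The NFAT target Il2, the T cell growth factor, was at the floor in wild-type LPS cells and had signals of 127 and 115 with thapsigargin, at least 9.02-fold higher, without passing (adjusted p = 0.101).

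Camera ranks a list against all other genes, and the median change with thapsigargin in wild-type cells over all genes was 0.11. By this test, 8 neutrophil markers ranked lower (median −1.37, 0 passed and 5 fell when adjusted over the list alone, camera adjusted p = 1.7e-10, adjusted p = 0.133 with an estimated correlation). The 35 endoplasmic reticulum stress genes ranked higher (median 0.64, 0 passed and 12 rose when adjusted over the list alone, camera adjusted p = 7.3e-07), as did 33 interferon-response genes (median 0.49, 0 passed and 3 rose when adjusted over the list alone, camera adjusted p = 2.0e-06). The 32 NF-κB and inflammatory genes ranked lower with a median near no change (−0.05, 0 passed and 5 fell when adjusted over the list alone, camera adjusted p = 0.000459), and for these 3 lists the adjusted p = 0.404 with an estimated correlation. The 19 p53 and damage genes ranked higher (median 0.48, 0 passed and 4 rose when adjusted over the list alone, camera adjusted p = 0.000275, adjusted p = 0.247 with an estimated correlation). The 13 macrophage markers ranked lower (median −0.84, 0 passed, also when adjusted over the list alone, camera adjusted p = 0.000680, adjusted p = 0.586 with an estimated correlation). The 10 heat shock genes also ranked lower with a median near no change (−0.10, 0 passed and 1 fell when adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.477 with an estimated correlation).

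The thapsigargin effect was not shown to differ between genotypes for any single gene: 0 genes passed by limma, with 994 at an unadjusted p under 0.05, and that count was 381 and 1899 without the CD14-deficient LPS array at 48 or at 60 h, 5 without a filter and 2 without the intensity trend. The wild-type count of 4 was 586 and 594 without the CD14-deficient LPS array at 48 or at 60 h, 0 without any single one of the other 6 stimulated arrays, 7 without a filter, 12 without the intensity trend and 9 without the 60 h term.

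The pattern the design selects for is a gene that is lower without CD14 under LPS and rises with thapsigargin. At 2-fold and at both times, 90 genes were higher in wild-type than in CD14-deficient LPS cells and raised by thapsigargin in CD14-deficient cells. They held 14 interferon-response genes and 3 of the 4 followed-up genes, Nr4a1, Ddit3 and Gadd45g, which are treated as chosen on these samples. The strongest by the mean of both changes were Cmpk2, Ccl7, Ifit3, Emp1, Csf3, Ifit2, Ms4a4c, Gprc5b, Mx2 and Rsad2. Of these 10, Mx2 passed neither test (adjusted p = 0.0859 and 0.0865), and Ccl7 and Csf3 with thapsigargin stayed below wild-type LPS cells by log2 2.17 and 2.34. Ccl7, Emp1 and Ifit2 were not 2-fold above the unstimulated array at both times in wild-type LPS cells (log2 change 0.35, −0.12 and 0.94). Of the 90, 74 were also 2-fold above the unstimulated wild-type array at both times in wild-type LPS cells, and 74 passed both tests. With thapsigargin the 90 genes differed in CD14-deficient cells from wild-type LPS cells by a median log2 of −0.01, with 9 of them at least 2-fold below and 4 at least 2-fold above. Choosing genes on both changes over the same CD14-deficient LPS arrays puts this median near 0, so it does not measure restoration. In wild-type cells their median change with thapsigargin was 0.27.

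The mirror set, lower in wild-type LPS cells and lowered by thapsigargin in CD14-deficient cells, held 133 genes, 9 of them of cell division, and 81 passed both tests. The 5 with the largest mean of both changes were C1s1, Igha, Ube2c, Septin4 and Aif1. C1s1, Igha and Ube2c were among 13 of the 133 genes under the floor in CD14-deficient cells with thapsigargin at both times, so their falls are lower bounds and their order is not determined. Only 3 and 1 genes went in opposite directions in the comparisons. Because both comparisons use the same CD14-deficient LPS arrays, 100 simulations without effects were run, and they gave a mean of 2.10 and at most 5 restored genes and a mean of 2.05 and at most 5 mirror genes. Their noise was drawn independently per gene and with the same spread on all arrays. They thus hold no departure of a whole array and no larger spread on the shared arrays. Independent lists would share 4.54 and 9.95. Across genes, which are not independent replicates, the comparisons correlated at Pearson's r = 0.702, against a mean of 0.501 in the simulations. A larger spread on the shared arrays raises r without effects. The SD between 48 and 60 h was 0.830 in CD14-deficient LPS cells, 0.518 in wild-type LPS cells and 0.389 in CD14-deficient cells with thapsigargin. The difference from 0.501 therefore does not measure correlation beyond the shared arrays.

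With different CD14-deficient LPS arrays for the comparisons, 135 genes were 2-fold up in both with genotype at 48 h and 157 with genotype at 60 h, where independent lists would share 62.5 and 34.5. Down in both were 219 and 230, where they would share 119 and 70.2. In the same direction there were thus 354 and 387 genes, and in opposite directions 207 and 66. Of the genes higher in wild-type cells, 153 and 16 were lowered by thapsigargin, beside the 135 and 157 raised. The restored count was 460 at 48 h alone and 246 at 60 h alone, 236 at 1.5-fold and 28 at 3-fold. Of the 387 genes that differed between the genotypes under LPS, 2 were called between the genotypes under LPS with thapsigargin, and 15 between CD14-deficient cells with thapsigargin and wild-type LPS cells. These comparisons called only 2 and 28 of 7474 genes in all. The small overlaps therefore do not show that thapsigargin removed the other differences.

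**Figure D3:**
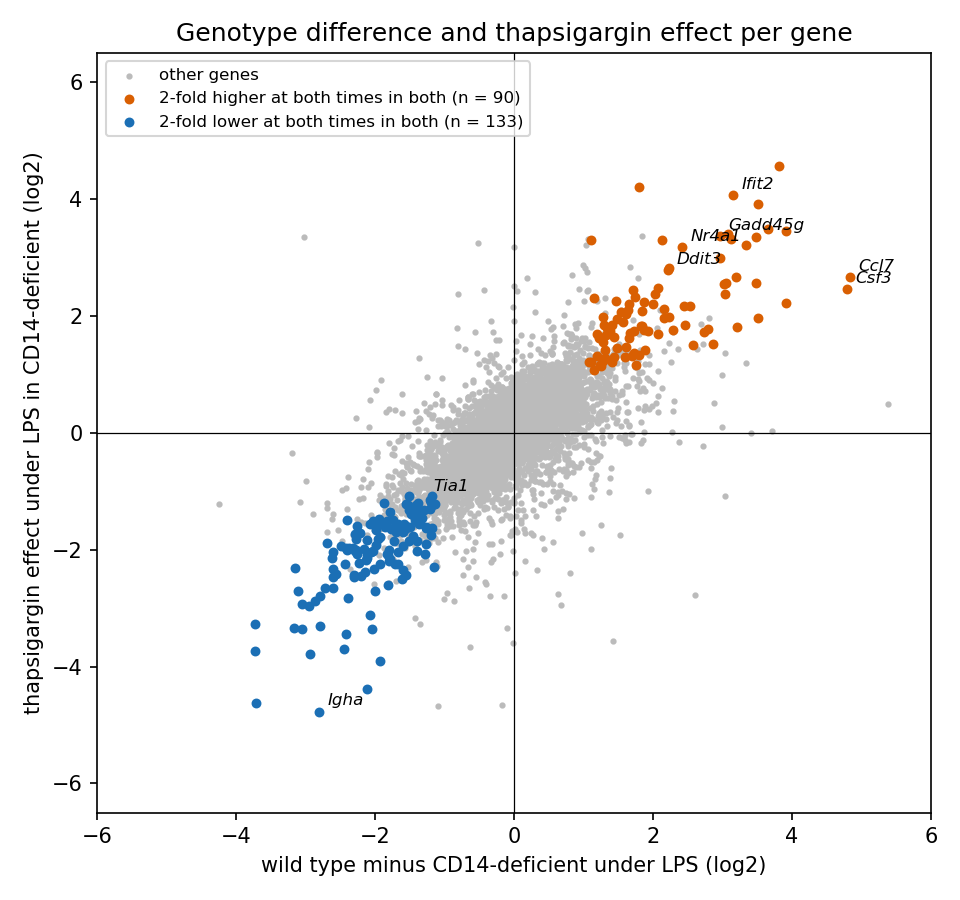
Each tested gene by its log2 difference between wild-type and CD14-deficient LPS cells (horizontal axis) and its log2 change with thapsigargin in CD14-deficient LPS cells (vertical axis), averaged over 48 and 60 h. The 90 genes 2-fold higher and the 133 genes 2-fold lower at both times in both comparisons are coloured. Both axes use the same CD14-deficient LPS arrays, so genes without any effect also slope upward. The r was 0.702 here and 0.501 in simulations with equal spread on all arrays. The shared arrays had a larger spread than the others, which raises r without effects, so 0.501 is no limit for it.

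Averaged over LPS and LPS with thapsigargin, 97 genes were higher and 56 lower in wild-type cells, 153 in all with 4 arrays against 4. Cd14 had the smallest adjusted p (2.48e-06), and Erdr1 (5.03, adjusted p = 0.000361) and Ccl7 (3.18, adjusted p = 0.010) were also higher. Averaged over genotypes, thapsigargin raised 247 and lowered 204 genes, 451 in all. The genotype count was 22 without a filter, 101 with a strict filter, 932 and 2801 without the CD14-deficient LPS array at 48 or at 60 h and 3 or 4 without any single other stimulated array. The thapsigargin count was 201 without a filter, 2476 and 2482 without those LPS arrays, and between 0 and 7 without any single other stimulated array.

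Between 48 and 60 h, averaged over the 4 stimulated conditions, 0 genes passed by limma, with 734 at an unadjusted p under 0.05, and the count was 99 and 101 without the CD14-deficient LPS array at 48 or at 60 h. By camera, with a median of 0.05 over all genes, the 11 MHC class II genes ranked lower at 60 h (median −0.32, 0 passed and 5 fell when adjusted over the list alone, camera adjusted p = 3.1e-07, adjusted p = 0.618 with an estimated correlation). The 13 NFAT target genes ranked higher (median 0.53, 0 passed, also when adjusted over the list alone, camera adjusted p = 0.00916, adjusted p = 0.618 with an estimated correlation). Interferon-response genes (median −0.21, camera adjusted p = 0.00849), maturation genes (median −0.12, camera adjusted p = 0.00434) and endoplasmic reticulum stress genes (median −0.11, camera adjusted p = 0.0283) ranked lower, with 0 members passing and adjusted p = 0.745 with an estimated correlation for each.

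Between the unstimulated arrays, 1 against 1, Cd14 was the only gene that passed, and 41 genes were 2-fold higher and 58 were 2-fold lower in wild-type cells. The list with the smallest camera p was that of 27 cell division genes, lower in wild-type cells by a median log2 of −0.44. With 1 array on each side, the test takes its spread from other conditions. It cannot tell a difference between the genotypes from one between the 2 cultures. The count of 1 was 176 without a filter and 2 without the 60 h term.

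**Figure D4:**
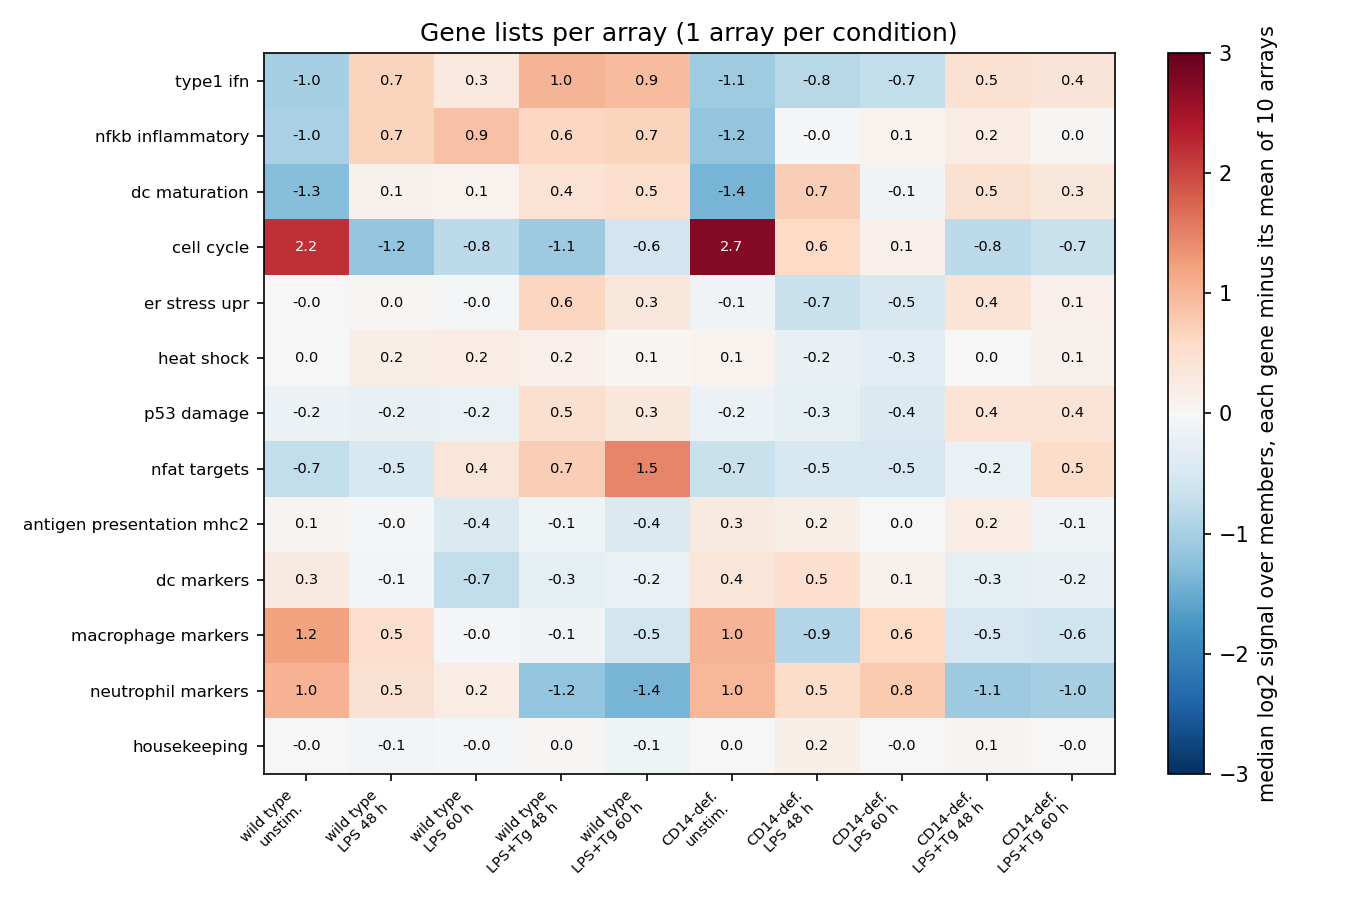
Median log2 signal of 13 gene lists (vertical axis) on each of the 10 arrays (horizontal axis), each gene taken relative to its mean over the arrays, with colour and printed value giving the median in log2 units. Interferon-response genes lie at −0.84 and −0.73 on the CD14-deficient LPS arrays, against 0.66 and 0.29 in wild-type LPS cells and 0.46 and 0.40 in CD14-deficient cells with thapsigargin.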

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

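The tests of 3-prime bias, of macrophage-like cells and of a compressed signal range, the simulations at a single time, the medians over all list members, the slopes on the 60 h array and the overlap of the 2 times were chosen after the results they address had been seen, and the others before.

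The CD14-deficient LPS array at 48 h stood apart from the other 9 arrays, at 60.42 on the second principal component against −25.02 to 5.12. A different scale or shape of its signal distribution was argued against, since 1277 genes were still 2-fold apart from its 60 h partner after quantile normalization, against at most 424 in the other 3 conditions. A bias toward the 3-prime end of the labelled RNA stays open: the Gapdh 3-prime over 5-prime ratio was log2 −0.03 against −0.49 to −0.24 on the other arrays, but that of Actb was 0.16, inside their range of 0.03 to 0.70. Another difference in RNA or labelling stays open too, since its 18S rRNA signals of 114 and 269 and the 217 and 396 of the wild-type LPS array at 60 h lay under the 1426 to 11926 of the other 8 arrays, and these 2 arrays had the lowest cRNA yields. Fewer macrophage-like cells in that culture may also account for it, with macrophage markers at a median log2 of −1.87 against 60 h (0.11 to 0.46 in the other conditions), but dendritic cell markers, which should then have been higher than elsewhere, differed by 0.27, inside the 0.03 to 0.34 of the other conditions, with 9 of 14 higher. With 1 array per time, fewer such cells cannot be told apart from a change over time in the same cells. Lysosomal and matrix genes moved with the macrophage markers (median −2.92) and genes of migratory dendritic cells against them (1.17), in lists written after the component had been seen.

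Of the 1191 genes that LPS changed in wild-type cells, 1062 changed less in CD14-deficient cells, a count raised by choosing genes on their wild-type change, but of the 312 called in CD14-deficient cells 177 also changed more in wild-type cells and 135 less. A share of cells that did not respond would give every group of induced genes a like share of the wild-type response on the linear scale. This holds only if each cell responds on its own and time in culture plays no part, which was not tested. The 13 maturation genes reached a median of 0.902 and 20 interferon-response genes 0.146, a difference of 0.756 (bootstrap 95% interval over genes 0.520 to 1.15). A compressed signal range on the CD14-deficient LPS arrays would lower all groups alike on the log2 scale, and the difference there was 0.706 (0.473 to 1.17). That argues against a compressed range as the whole cause, and against a share of non-responding cells only under the conditions above. Over all 23 maturation and 33 interferon-response genes, not chosen by their change, the median log2 change in CD14-deficient cells was 1.47 and 0.0669 times that in wild-type cells, a difference of 1.40 (0.767 to 3.60), and on the linear scale 2.69 (1.14 to 7.23). A fault in the RNA or labelling of the 48 h array was likewise argued against as the whole cause: on the 60 h array alone the changes had a slope of 0.645 on the wild-type ones, below the 0.943 of the thapsigargin array at 60 h on the same genes (difference 0.297, 0.261 to 0.332), and maturation genes exceeded interferon-response genes by 0.639 (0.390 to 0.848). The first 2 differences and these slopes use genes called in wild-type cells, each genotype was a single culture per time, and a difference between the mice or cultures other than Cd14 was not tested. The bootstrap resampled genes measured on the same arrays, so its intervals cover the spread among genes and not among cultures or arrays.

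The 90 genes higher in wild-type LPS cells and raised by thapsigargin in CD14-deficient cells rest on CD14-deficient LPS arrays that both comparisons use. The overlap of the 2 times argued against the 48 h array alone as the source of the set. It also argued against noise of the 1 array shared at each time that is independent between genes and between times. Of the 460 genes with the pattern at 48 h, on arrays that the 60 h pattern does not use, 90 had it at 60 h and 24 its mirror, where independent lists would share 15.1 and 21.3. At 60 h alone 246 genes had the pattern, against 28.1 for independent lists and at most 58 in simulations without effects that share the array. These simulations drew noise independently per gene and with the same spread on all arrays. The log2 differences between 48 and 60 h had an SD of 0.830 in CD14-deficient LPS cells. It was 0.518 in wild-type LPS cells and 0.389 in CD14-deficient cells with thapsigargin. The count at 60 h thus excludes neither more noise on the shared array nor a departure of that whole array. A departure common to both CD14-deficient LPS cultures stays open, since both comparisons use them. With different arrays and genotype at 48 h, 135 genes were up and 219 down in both, 354 in the same direction against 181 for independent lists, and 207 in opposite directions against 173, with more of the genes higher in wild-type cells lowered (153) than raised (135) by thapsigargin. With genotype at 60 h, 157 were up and 230 down in both, 387 against 105, and 66 in opposite directions against 98.4. The number of restored genes beyond the shared arrays is thus not fixed, and a thapsigargin effect on stress genes that does not pass through NFAT was not tested, since no cells received thapsigargin alone.

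Gene lists differed between the genotypes in their response to LPS, wild-type minus CD14-deficient, by camera with the preset correlation, and none did with an estimated correlation (adjusted p from 0.292 to 0.407). The median log2 difference was 2.48 for the 4 followed-up genes, 1.30 for interferon-response genes, 0.89 for NFAT targets, 0.70 for NF-κB and inflammatory genes, 0.62 for endoplasmic reticulum stress genes, 0.57 for glycolysis and hypoxia genes and 0.45 for heat shock genes. It was −0.91 for cell division genes, −0.63 for dendritic cell markers and −0.41 for the NFAT machinery. In the response to thapsigargin, CD14-deficient minus wild-type, the medians were 2.51 for the followed-up genes, 0.88 for interferon-response genes, 0.59 for NF-κB and inflammatory genes, 0.41 for endoplasmic reticulum stress genes, 0.39 for p53 and damage genes, 0.32 for heat shock genes and −1.12 for cell division genes, and none was called with an estimated correlation (adjusted p from 0.335 to 0.397).

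Some genes were 2-fold apart in opposite directions at 48 and 60 h, a difference that was not tested: 108 between the genotypes under LPS, 48 for thapsigargin in CD14-deficient cells, 21 for LPS in CD14-deficient cells, 3 for thapsigargin in wild-type cells and 1 for LPS in wild-type cells. The LPS counts cannot be set beside the other 3, because their 2 times share 1 unstimulated array, which makes opposite directions rarer. Among 991 probe sets without a single gene symbol that passed the filter on dim signals, of 2246 such probe sets, 133 were called for LPS in wild-type cells and 42 in CD14-deficient cells.

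Over the 8 stimulated arrays, all 35 splits into 4 against 4 were fitted with the split alone. The thapsigargin split called 82 genes, the most of all, against 10 for the next (1 of 35 as large). Chance was still not excluded for it, since genotype, thapsigargin and time were each tried. The splits also ignore the matching of arrays on genotype and time, and each condition was a single culture. Nor was chance excluded for genotype, whose split called 10 genes, because 2 of the 35 called as many. The other of these was the thapsigargin split with 82, which points to a structure of the samples that the design names. The other 33 splits called 0 genes, and with thapsigargin ranked first genotype could reach 2 of 35 at best, above the limit of 5%. For 60 h against 48 h the split called 0 genes and the highest other 82, and since any split calls at least 0, the 35 of 35 as large say nothing about chance.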

How the results depend on the processing

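The fits that took other time points or other pairings of arrays were chosen after seeing the data, and all other alternatives before. Quantile normalization and a pseudocount in place of the floor kept each count within 1.5 times, and only the filters, the fold thresholds, the left-out arrays and a few other choices moved any. Without a filter, counts were 105 for wild type against CD14-deficient cells under LPS, 192 for the difference of LPS responses, 7 for thapsigargin in wild-type cells, 153 for thapsigargin in CD14-deficient cells, 5 for the difference of thapsigargin effects, 22 for genotype and 201 for thapsigargin over 8 arrays, and 176 between the unstimulated arrays. Under the strict filter they were 770 and 147 for LPS in wild-type and CD14-deficient cells and 101 for genotype over 8 arrays. The balance of higher to lower genes was not stable. For LPS in wild-type cells, 575 to 616, it was 672 to 597 with quantile normalization and 416 to 354 under the strict filter. For LPS in CD14-deficient cells, 162 to 150, it was 76 to 239 without a filter, 98 to 49 under the strict filter, 158 to 166 with a pseudocount and 139 to 169 without the intensity trend. For genotype under LPS, 195 to 192, it was 202 to 207 with a pseudocount, 190 to 230 without the trend and 197 to 203 without the 60 h term, and for thapsigargin in CD14-deficient cells, 256 to 239, it was 249 to 269 without the trend. For genotype over the 8 stimulated arrays, 97 to 56, it was 70 to 67 without the trend. At both times, quantile normalization turned LPS from 608 to 728 into 700 to 660 in wild-type cells and from 344 to 358 into 370 to 350 in CD14-deficient cells, and the strict filter gave 405 to 359 and 208 to 152. At 1.5-fold, thapsigargin in wild-type cells gave 319 to 292, against 82 to 130, and LPS in CD14-deficient cells 749 to 739. For genotype under LPS, 164 to 247 at both times became 107 to 107 under the strict filter and 59 to 60 at 3-fold. Without the intensity trend, 12 genes passed for thapsigargin in wild-type cells and 2 for the difference of thapsigargin effects, and without the 60 h term 9 passed for thapsigargin in wild-type cells and 2 between the unstimulated arrays. Without a floor, 1 gene passed for the difference of LPS responses, and Cd14 in CD14-deficient cells, under the floor on all arrays and so without a change in the report, fell by 1.39 with thapsigargin. The cause was not tested for these, except that more or fewer genes were tested with another filter.

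Leaving out single arrays gave ranges of 170 to 3281 for LPS in wild-type cells, 22 to 2883 for LPS in CD14-deficient cells, 2 to 3309 for genotype under LPS, 0 to 1367 for the difference of LPS responses, 0 to 594 and 0 to 2894 for thapsigargin in wild-type and CD14-deficient cells, 0 to 1899 for the difference of thapsigargin effects, 3 to 2801 for genotype and 0 to 2482 for thapsigargin over 8 arrays, and 0 to 101 for 60 h against 48 h. The high ends came without either CD14-deficient LPS array, and the low ends without another stimulated array. Leaving out any stimulated array lowers the residual degrees of freedom from 3 to 2, so this loss alone does not give the high ends. Without either CD14-deficient LPS array, the gap of that condition between 48 and 60 h leaves the residual. That gap was the largest, with 1297 genes 2-fold apart against at most 491 in the other conditions. It widens the errors of comparisons that do not use these arrays. For the low ends, the lost degree of freedom and the lost array were not separated. The number of called genes is therefore not a stable property of these data. Among the values of named genes under these alternatives, 1 changed sign with a call, that of Cd14 above, and 34 without one, while 1182 lost a call and 216 gained one at an unchanged sign.

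Genes 2-fold apart at both times numbered 214, 116, 287, 764 and 360 under the strict filter for genotype under LPS, thapsigargin in wild-type cells, thapsigargin in CD14-deficient cells, LPS in wild-type cells and LPS in CD14-deficient cells. In the same order they numbered 1023, 611, 1281, 2594 and 1488 at 1.5-fold and 119, 74, 178, 668 and 336 at 3-fold, and at 60 h alone the first 3 were 957, 407 and 1200. The restored genes numbered 236 at 1.5-fold, 28 at 3-fold, 460 at 48 h alone, 246 at 60 h alone and 157 with genotype at 60 h paired with thapsigargin at 48 h. Under the strict filter the restored and mirror sets held 61 genes each, against 90 and 133, so the larger mirror set depends on the filter. Of 35 camera calls of the fixed lists in the 5 main comparisons, 0 held with an estimated correlation. That test rests on 3 residual degrees of freedom and passed in 0 of 115 cases, so it has little power here. It cannot decide whether the calls with the preset correlation hold.

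For the followed-up genes, Nr4a1 kept a log2 difference of 1.62 to 3.21 between the genotypes and 2.38 to 3.97 with thapsigargin in the 18 alternatives that gave it a value, which leaves out the strict filter. In 19 alternatives Ddit3 kept 1.55 to 2.89 and 2.11 to 3.46, and Gadd45g 2.49 to 3.44 and 2.89 to 3.84. The calls of all 3 in both comparisons ended without a filter. Between the genotypes they held in 4 of 10 fits without an array, with adjusted p up to 0.228, 0.257 and 0.172, and with thapsigargin in 6 of 10, with adjusted p up to 0.262, 0.212 and 0.188. Among 137 genes of the sets or named by the rule with more than 1 probe set past the filter, 5 had another probe set 2-fold in the opposite direction in a main comparison, Irf4 among them. Dim genes were limited by signal over background: 4919 of 12393 genes did not pass the filter, and folds against a group at the floor are lower bounds. An LPS comparison without its own unstimulated array, or on the 8 stimulated arrays alone, could not be fitted, nor could 60 h against 48 h without its term.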

Other observations

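The gene sets described here, other than those fixed in advance, were chosen after their values had been seen. Sterol synthesis genes, written as a list after the principal components had been seen, ranked lower with LPS in wild-type cells: 6 of 19 fell and 13 did not pass (12 fell when adjusted over the list alone), with a median log2 of −1.0 (camera adjusted p = 2.3e-05, adjusted p = 0.195 with an estimated correlation). In CD14-deficient cells 3 of 19 fell (median −0.99, camera adjusted p = 9.9e-07, adjusted p = 0.181 with an estimated correlation). Of 8 acute phase genes, LPS raised 7 in wild-type cells (median 5.01, camera adjusted p = 5.0e-08, adjusted p = 0.195 with an estimated correlation) and 4 in CD14-deficient cells (median 3.69, camera adjusted p = 2.7e-08, adjusted p = 0.187 with an estimated correlation). With thapsigargin in wild-type cells they ranked lower (median −1.68, 1 of 8 fell, 6 when adjusted over the list alone, camera adjusted p = 3.4e-13, adjusted p = 0.195 with an estimated correlation). By camera, amino acid supply genes ranked higher with thapsigargin in wild-type cells (median 0.62, 0 of 19 passed, camera adjusted p = 0.000718, adjusted p = 0.195 with an estimated correlation). Of 17 genes of migratory dendritic cells, 3 rose with LPS in CD14-deficient cells and 14 did not pass (14 rose when adjusted over the list alone), with a median of 1.14 (camera adjusted p = 7.5e-08, adjusted p = 0.310 with an estimated correlation), while lysosomal and matrix genes ranked lower there (median −1.04, 0 of 19 passed, camera adjusted p = 0.0158, adjusted p = 0.569 with an estimated correlation). Both lists had been chosen once the component was known on which the CD14-deficient LPS array at 48 h lies apart. Relative to their mean over the arrays, the migratory genes had a median of −0.70 unstimulated, 1.2 at 48 h and 0.18 at 60 h. The lysosomal and matrix genes stood at 0.59, −1.53 and 1.06. With LPS and no thapsigargin, their median thus lay below the unstimulated one at 48 h and above it at 60 h, on 1 array each. With thapsigargin it lay at −0.56 and −0.50 at 48 and 60 h.

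Immunoglobulin genes were higher in CD14-deficient LPS cells than in the other stimulated cells. All 6 tested were at least 2-fold lower in wild-type LPS cells at both times, with a median log2 of −2.28 and 3 passing, and thapsigargin lowered 5 of the 6 in CD14-deficient cells, with a median of −3.57. The scaled signal of Ighm was 1789 and 1364 on the CD14-deficient LPS arrays, 160 and 512 on the wild-type LPS arrays and 74.9 and 193 on the CD14-deficient arrays with thapsigargin. Il2 was above the floor only with thapsigargin, at 127 and 115 in wild-type cells and at 27.5 on the CD14-deficient array at 60 h.

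In all 5 pairs of arrays matched on treatment and time, 13 genes were at least 2-fold apart between the genotypes in 1 direction, 8 higher and 5 lower in wild-type cells, while 1 gene was 2-fold apart in all 5 pairs with mixed directions. Besides Cd14, the mean log2 differences were 4.83 for Erdr1, −3.83 for BC023105, 2.76 for Ccl7, −2.71 for Gm6958, 2.34 for Rpgrip1, 2.12 for Wdfy1, −1.99 for Klrb1b, 1.94 for Rhou, 1.92 for Ghitm, 1.61 for U90926, −1.52 for Dhrs7 and −1.31 for Cdk5rap1. The scaled signal of Erdr1 was between 4239 and 8191 on the wild-type arrays and between 168 and 305 on the CD14-deficient arrays, unstimulated arrays included. Whether background strain or sex of the mice gave these differences was not tested.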
